A study of Homo sapiens with 42 samples.

How the data were processed

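Total RNA of 1205Lu melanoma cells was labelled with biotin and hybridised to 42 single-colour Illumina HT-12 bead arrays, 1 per sample. The samples were 4 controls at 0 h, and for AZD1152 (0.5 µM) and SNS-314 (0.05 µM) 3 samples each at 6 h and 4 each at 12, 18, 24 and 48 h. Per the file headers the first table is non-normalized, and its values are the intensity of each of 47312 probes on each array, with 0 negative values and no background subtracted. The second deposited table holds log2 values that were quantile normalized between arrays, with a median of 8.15 on every array. The steps the authors took to make that table are not given in the sources used here. The non-normalized table carries 2 header lines that contradict each other. The second was used, since it names the best matching deposited column for 42 of 42 columns (lowest rank correlation 0.999977, highest with another array 0.937), and the first does so for 1 of 42.

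Intensities were background corrected by the normexp model without control probes (offset 50), quantile normalized and put on the log2 scale in limma 3.58.1 under R 4.3.3. As the tables hold no detection p-values, the planned filter was replaced by a background threshold per array, set from the mode and the lower flank of the signal at the 95th percentile of background. A probe was kept if it lay above the threshold on at least 3 arrays of 1 group, which left 13481 probes. Symbols were updated through Entrez identifiers with the RefSeq annotation of GRCh38.p14, used for names only. Of all probes 30110 had 1 symbol, 8 had several and 17194 had none, and the last 2 kinds were left out. Each of 8917 genes was read from its brightest passing probe, and 1983 genes had more than 1. Where all arrays of a group lay below background, the fold change is given as a bound against the threshold. Arrays had a median signal of 210.0 to 338.6 and 20.5% to 30.4% of probes above background, and their number limits the precision, with a median SE of 0.113. With changes of known size simulated in the non-normalized values, 74.0% of genes changed 2-fold and 50.0% of genes changed 1.5-fold were called at 48 h. These shares were 78.0% and 28.0% at 6 h, and 80.0% and 36.0% for the difference of the inhibitors at 48 h. The simulated spread was taken from non-normalized values and drawn separately for each probe. It thus holds differences in level between whole arrays, which normalization removes from the real data, and the shares may be too low. The median fitted change for 2-fold at 48 h was 0.78, so folds are understated.

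A group-means model was fitted to all 42 arrays with limma for 17 comparisons: each inhibitor and time against 0 h (10), AZD1152 against SNS-314 at each time (5), and 48 h against 6 h in each inhibitor. A gene was called at a Benjamini-Hochberg adjusted p under 0.05 within its comparison. Gene lists (24) were written before the data were examined and tested by camera with a preset correlation of 0.01, with an estimated correlation beside it, adjusted over the lists with at least 3 measured genes. They cover DNA replication, mitosis, Aurora kinases and partners, p53 target genes, senescence core genes, secreted factors of senescent cells, NF-κB targets, interferon-stimulated genes, antigen presentation, melanocyte genes, lysosome, pro-death apoptosis effectors, replication-dependent histones, cholesterol synthesis, hypoxia, unfolded protein and amino acid stress, ERK output, YAP targets, ribosome biogenesis, extracellular matrix, and markers of fibroblasts, leukocytes, endothelium and keratinocytes. No list was called with its median, mean and test in different directions.

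Genes were named by a rule set before the data were examined: fixed genes of the Aurora kinases, senescence and proliferation, the called genes with the largest changes at 48 h (6 in each direction) and 6 h (3 in each direction), the 2 members of each list with the largest mean change at 48 h, and up to 4 called genes in each direction between the inhibitors at 24 and 48 h. Of the fixed genes AURKC and CDKN2A were not above background on any array with their 3 probes each, and were not measured.

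Chips were read from the column names: 4 chips held 12, 12, 6 and 12 arrays, with 2 controls each on chips 2 and 4. Residuals correlated with a median r of 0.179 within a chip and -0.08 between chips. Replicate numbers paired the arrays of both inhibitors at 6 h (residual r 0.150 to 0.277), 12 h (0.150 to 0.324) and 24 h (0.280 to 0.424), where every pair shared a chip. They did not pair at 18 h (-0.0491 to 0.401) or 48 h (0.0671 to 0.288). Alternatives were the deposited values, no background correction, scaling to the 75th percentile, no filter or a filter on all arrays, the mean over probes, an intensity trend with robust variances, only the groups compared, replicate or chip as a block, an estimated correlation, split controls, and leaving out each array. Chip as a fixed block and leaving out 3 arrays together were chosen after seeing the data. Agreement between the inhibitors was set against 20 simulations of unchanged groups. Figures were drawn with Python 3.11.15 and matplotlib 3.10.9.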

Results

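Gene expression was measured in 1205Lu cells, an established human metastatic melanoma line, on 42 single-colour Illumina bead arrays, 1 array per sample. Cells received AZD1152 (barasertib, an inhibitor selective for Aurora kinase B) at 0.5 µM or SNS-314 (an inhibitor of all Aurora kinases) at 0.05 µM. The Aurora kinases drive the alignment and separation of chromosomes and the final division of the cell. Cells were collected after 6 h (n = 3 per inhibitor) and after 12, 18, 24 and 48 h (n = 4 per inhibitor and time), and 4 control samples were taken at 0 h. The labels do not say whether replicates are separate cultures. P-values other than those of camera thus measure only the spread between these samples, which may be technical. Camera, the test of gene lists, sets the statistics of a list's genes against those of the other genes. With the preset correlation it treats the genes of a list as nearly independent, so its small p-values do not stand for strong agreement between replicates. The number of arrays limits the precision. The median signal per array was between 210.0 and 338.6, and 20.5% to 30.4% of probes lay above background. Replicates of a group correlated across genes with r from 0.968 to 0.994. Values below are log2 fold changes ± SE from limma over 8917 genes, with p-values adjusted by the Benjamini-Hochberg method within each comparison. All comparisons with 0 h hold both the inhibitor and the time in culture, since untreated cells of later times were not analysed here.

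The first comparison set each inhibitor at 6 h against the 0 h control and asks which transcripts move before cells have passed through a full division. The 3 genes that fell furthest with each inhibitor encode chemokines. CCL2, which encodes a monocyte attractant, fell by 3.39 ± 0.16 with AZD1152 (adjusted p = 9.3e-20, n = 3 and 4, limma) and fell by 3.43 ± 0.16 with SNS-314 (adjusted p = 6.4e-20). CXCL1 fell by 2.77 ± 0.33 with AZD1152 and fell by 2.59 ± 0.33 with SNS-314, and it was above background on 2 of 3 arrays of each 6 h group. CXCL8, which encodes the neutrophil attractant interleukin-8, fell by 2.17 ± 0.19 with AZD1152 and fell by 2.30 ± 0.19 with SNS-314. Of the 24 measured NF-κB target genes, genes switched on by the inflammatory transcription factor NF-κB, 19 were lower with each inhibitor and none was higher. The list's median was -1.005 with AZD1152 (camera adjusted p = 2.0e-73) and -0.95 with SNS-314 (adjusted p = 4.3e-63), and both calls held with an estimated correlation. Adjusted over the list alone, 23 and 22 members were lower.

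Further lists moved at 6 h with smaller medians. Of 21 lists tested, 8 (AZD1152) and 9 (SNS-314) were called with the preset correlation and 5 and 7 also with an estimated one. Not all of these are named here. The list of interferon-stimulated genes, which are part of the antiviral response, shifted by -0.22 with AZD1152 and by -0.30 with SNS-314, with 3 and 8 of 31 members lower, and 8 and 15 when adjusted over the list alone. IFIH1, a sensor of double-stranded RNA, fell by 0.86 ± 0.13 with AZD1152, where 2 of 3 arrays were above background. With SNS-314 IFIH1 was not above background on any array, which sets its fall at least 1.70-fold (adjusted p = 2.3e-08). Of 31 secreted factors of senescent cells, 11 and 12 were lower and 1 was higher, with medians of -0.19 and -0.11. Of all 31 factors 6 also stand in the NF-κB list. The YAP target list, genes of the growth pathway that senses cell shape and density, rose with medians of 0.28 and 0.24 (camera adjusted p = 2.3e-07 and 3.3e-06), with 4 and 3 of 17 members higher, and 9 and 6 when adjusted over the list alone. ERK pathway output, read from genes that ERK signalling induces, shifted by -0.04 and -0.16, with 3 of 19 members lower for each inhibitor. The calls of these lists held with an estimated correlation. Cholesterol synthesis genes had medians of 0.15 (adjusted p = 0.0121, and adjusted p = 0.0789 with an estimated correlation) and 0.26 (adjusted p = 0.0023, and adjusted p = 0.0277 with an estimated correlation). The p53 target genes had medians of 0.12 and 0.13, with calls that were lost with an estimated correlation (adjusted p = 0.0933 and adjusted p = 0.107).

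Genes with other functions rose at 6 h. RDH10, a retinol dehydrogenase, rose by 1.33 ± 0.13 with AZD1152 and 1.32 ± 0.13 with SNS-314. DDAH1, which breaks down an inhibitor of nitric oxide synthesis, rose by 1.30 ± 0.13 and 1.35 ± 0.13. NNMT, a nicotinamide methyltransferase, rose by 1.28 ± 0.24 and 1.08 ± 0.24, and TAGLN, an actin-binding protein of contractile cells, by 1.21 ± 0.16 and 1.38 ± 0.16. DNA replication and mitosis genes had 0 called members of 40 and of 52 with either inhibitor at 6 h. The medians of the replication list were 0.06 and 0.02, and those of the mitosis list were 0.07 and 0.05. In all, 240 genes changed with AZD1152 (107 higher, 133 lower) and 331 with SNS-314 (172 higher, 159 lower), of which 26 and 31 changed at least 2-fold. The AZD1152 count was 151 without its replicate 2 and 141 without its replicate 3, and the SNS-314 count was 218 without its replicate 2. Controls were hybridised on 2 of the 4 chips, and within these chips the NF-κB medians were -1.003 and -0.83 with AZD1152 and -0.95 and -0.93 with SNS-314.

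**Figure D1:**
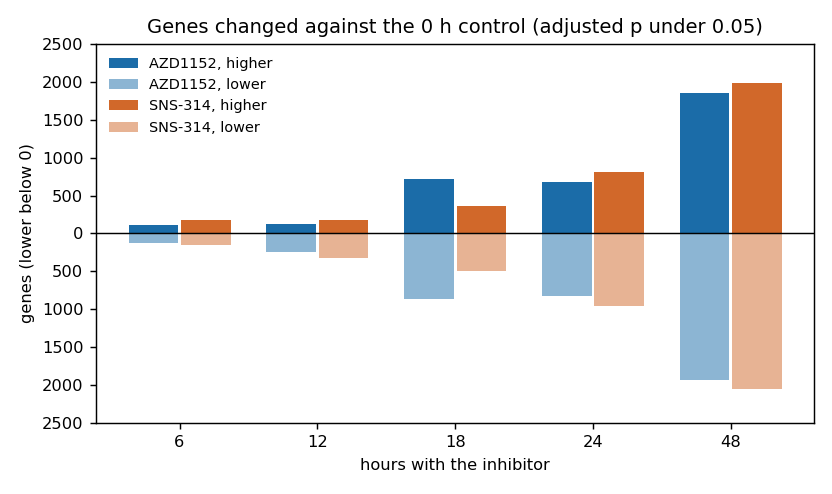
Number of genes changed against the 0 h control (limma, Benjamini-Hochberg adjusted p under 0.05) at each time in hours, with genes that were higher above 0 and genes that were lower below 0. Counts for AZD1152 and SNS-314 were 240 and 331 at 6 h and 3791 and 4036 at 48 h.

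The comparisons at 12 and 18 h ask how the response unfolded over the first cell cycle. DNA replication genes, targets of the E2F factors that start S phase, were the first cell cycle group to fall. At 12 h, 13 of their 40 measured members were lower with AZD1152 (median -0.28, camera adjusted p = 9.8e-12) and 19 with SNS-314 (median -0.33, adjusted p = 1.75e-13), or 23 and 25 when adjusted over the list alone. E2F2, one of these factors, fell with log2 changes of -0.65 ± 0.12 and -0.86 ± 0.12, and CDC45, a part of the replicative helicase, with changes of -0.56 ± 0.11 and -0.51 ± 0.11. In the same cells the mitosis list rose, with medians of 0.21 (adjusted p = 8.7e-11, 5 of 52 members higher) and 0.23 (adjusted p = 2.4e-10, 7 members higher). Adjusted over the list alone, 8 and 13 were higher, and 1 was lower with SNS-314. AURKA had values of 0.28 ± 0.10 and 0.33 ± 0.10 at 12 h, which did not pass the test (adjusted p = 0.13 and 0.053).

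At 18 h replication genes were lower still, with 32 and 33 members lower (33 and 34 adjusted over the list alone) and medians of -0.64 and -0.67, while the mitosis medians were -0.02 and -0.01 and did not pass the test (camera adjusted p = 0.742 and 0.707). The p53 target genes, which are induced by the tumour suppressor p53 after DNA damage and other stress, had risen by then. Their medians were 0.17 and 0.26 at 12 h and 0.45 and 0.30 at 18 h, with 22 and 13 of 34 members higher at 18 h, or 23 and 22 adjusted over the list alone (camera adjusted p = 2.5e-11 and 1.2e-10). GDF15, a stress-induced cytokine in that list, had already risen by 0.79 ± 0.15 and 0.65 ± 0.15 at 12 h. NF-κB target genes were still lower, with medians of -0.70 and -0.72 at 12 h and of -0.78 and -0.63 at 18 h. All these calls held with an estimated correlation. The counts of changed genes were 381 and 498 at 12 h and 1582 and 867 at 18 h, for AZD1152 and SNS-314. Without AZD1152 18 h replicate 1 the 18 h count was 1002, and without 3 arrays that stood apart from their groups it was 663, a choice made after seeing the data. At 12 h the AZD1152 count was 251 without its replicate 3, 236 without its replicate 4 and 252 without control replicate 3, and the SNS-314 count was 330, 293 and 325 without its replicates 3 and 4 and control replicate 4. With only the 2 groups compared in the fit, the counts were 551 for AZD1152 at 18 h and 240 for SNS-314 at 12 h.

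At 24 h the mitosis genes had turned lower as well. Of 52 members, 31 were lower and 1 was higher with each inhibitor, with a median of -0.42 in both (camera adjusted p = 1.7e-17 and 4.5e-16), and 40 and 39 were lower when adjusted over the list alone. AURKB, the kinase that AZD1152 targets, fell by 0.96 ± 0.14 with AZD1152 (adjusted p = 2.2e-06) and fell by 0.97 ± 0.14 with SNS-314 (adjusted p = 1.5e-06), and AURKA fell with changes of -0.34 ± 0.10 and -0.37 ± 0.10. Of 10 measured Aurora kinases and partner proteins, 7 and 6 were lower, with medians of -0.38 and -0.37, and 5 of these 10 also stand in the mitosis list. Of 40 replication genes, 36 were lower with each inhibitor (medians -0.74 and -0.80), or 39 and 38 when adjusted over the list alone. CDKN1A, which encodes the cell cycle inhibitor p21, rose by 0.63 ± 0.09 and 0.62 ± 0.09 (adjusted p = 2.8e-06 and 3.5e-06). The p53 target list had medians of 0.40 and 0.38, with 22 and 19 members higher, or 24 and 25 when adjusted over the list alone. NF-κB target genes were lower with medians of -0.67 and -0.76, with 20 of 24 members lower in each case. These list calls held with an estimated correlation. In all, 1495 genes changed with AZD1152 (674 higher, 821 lower) and 1766 with SNS-314 (812 higher, 954 lower). Within the 2 chips that hold controls the mitosis medians were -0.31 and -0.46 with AZD1152 and -0.26 and -0.45 with SNS-314.

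Smaller shifts at 24 h were called with the preset correlation in both inhibitors. Secreted factors were lower with medians of -0.17 and -0.18, with 11 of 31 members lower and 2 higher for each, and these calls held with an estimated correlation (adjusted p = 0.0025 and 0.0017). The hypoxia list was higher with medians of 0.06 and 0.15 (adjusted p = 0.108 and 0.0342 with an estimated correlation). Cholesterol synthesis genes were higher with medians of 0.18 (adjusted p = 0.0704 with an estimated correlation) and 0.42 (adjusted p = 0.0019 with an estimated correlation). The interferon list was lower with medians of -0.15 and -0.13 (adjusted p = 0.070 and 0.076 with an estimated correlation). The unfolded protein and amino acid stress list was higher with medians of 0.28 and 0.24 (adjusted p = 0.116 and 0.064 with an estimated correlation), and ribosome biogenesis was lower with medians of -0.23 and -0.24 (adjusted p = 0.108 and 0.076 with an estimated correlation). Lysosome genes had a median of 0.070 with AZD1152 (camera adjusted p = 0.047, and adjusted p = 0.237 with an estimated correlation) and of 0.069 with SNS-314 (camera adjusted p = 0.185). The AZD1152 call was lost without AZD1152 24 h replicate 1 (median 0.043) or replicate 2 (0.088), or control replicate 1 (0.084) or 3 (0.064).

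**Figure D2:**
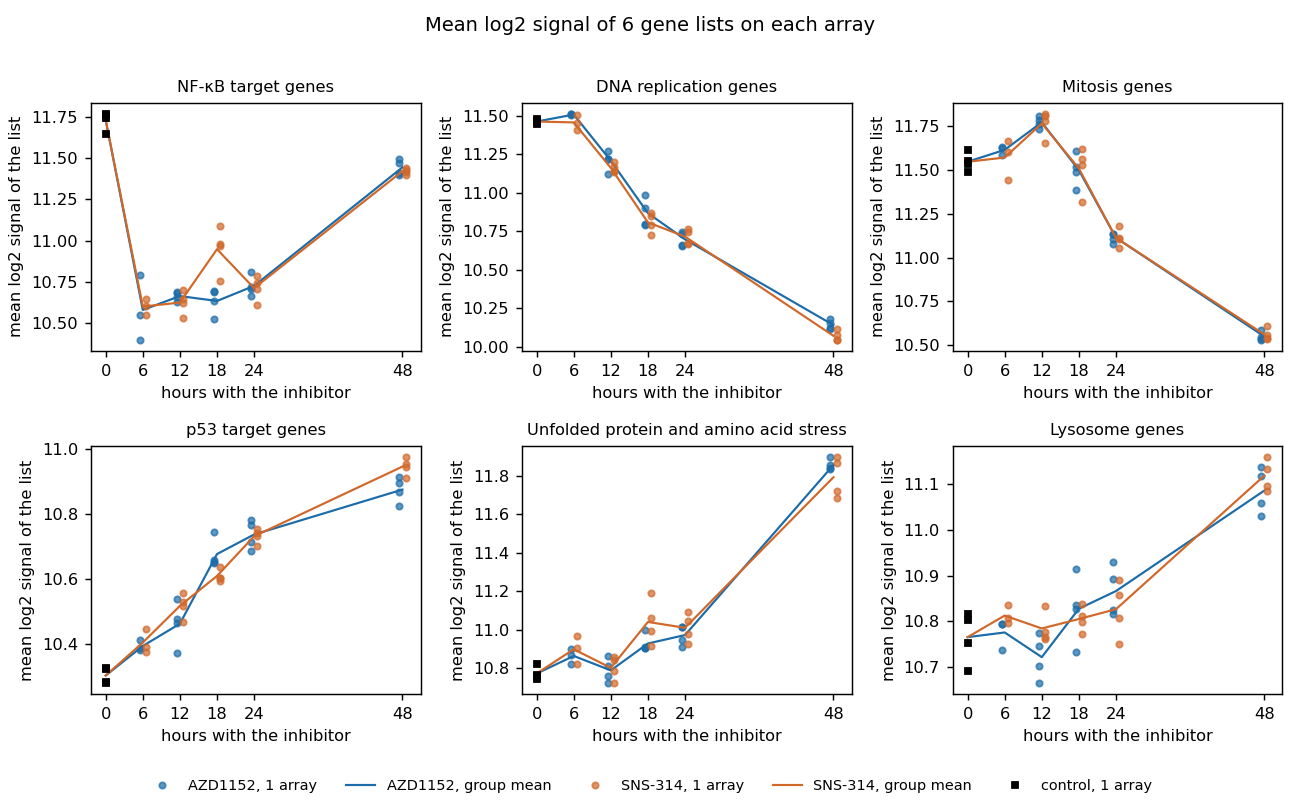
Mean normalized log2 signal of the measured members of 6 gene lists against hours with the inhibitor. Each point is 1 array, squares are the 4 control arrays, and lines join the control mean and the group means of AZD1152 and SNS-314. NF-κB target genes were lowest between 6 and 24 h and closer to the control at 48 h, replication genes fell from 12 h on, and mitosis genes were higher at 12 h and lower from 24 h on.

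The comparison at 48 h asks what the cells expressed at the end of the series, whose title names senescence, a lasting exit from division. All 40 measured DNA replication genes were lower with both inhibitors, with medians of -1.37 (camera adjusted p = 4.15e-42) and -1.38 (adjusted p = 1.6e-41), and so were all 52 mitosis genes, with medians of -1.03 and -1.01 (adjusted p = 1.3e-31 and 6.9e-29). RRM2, a subunit of ribonucleotide reductase, fell by 1.99 ± 0.21 with AZD1152 and fell by 1.69 ± 0.21 with SNS-314. GINS2, a part of the replicative helicase, fell with changes of -1.84 ± 0.11 and -2.03 ± 0.11, and UHRF1, which maintains DNA methylation, with changes of -1.81 ± 0.09 and -1.98 ± 0.09. E2F2, EXO1 and CDC45 fell with changes of -1.80, -1.74 and -1.69 with AZD1152 and of -1.94, -1.91 and -1.94 with SNS-314, each with SE 0.11 or 0.12. AURKB fell with changes of -1.54 ± 0.14 and -1.53 ± 0.14, and AURKA with changes of -1.04 ± 0.10 and -0.92 ± 0.10. CDCA8, a partner of Aurora B, fell with changes of -1.22 ± 0.14 and -1.27 ± 0.14, and TACC3, a partner of Aurora A on the spindle, with changes of -1.30 ± 0.10 and -1.34 ± 0.10. The proliferation marker MKI67 was above background on 3 of 4 control arrays and on no array at 48 h, so it fell at least 1.59-fold and 1.62-fold (adjusted p = 1.1e-10 and 3.4e-10). Of the Aurora kinases and partners, 8 of 10 were lower, with medians of -1.06 and -1.02.

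The p53 target list had medians of 0.53 (camera adjusted p = 2.9e-10) and 0.61 (adjusted p = 9.6e-12) at 48 h, with 25 and 27 of 34 members higher and 1 lower, and 27 higher and 1 lower with each inhibitor when adjusted over the list alone. GDF15 rose further than any other measured gene, by 2.74 ± 0.15 and 2.69 ± 0.15. SPATA18, a mitochondrial quality control gene, rose by 1.05 ± 0.13 and 1.29 ± 0.13, with 2 of 4 control arrays above background, and CDKN1A rose by 0.89 ± 0.09 and 0.93 ± 0.09. Senescence core genes, a list that mixes genes that rise and genes that fall in senescent cells, split evenly. With AZD1152 5 of 19 were higher and 5 lower, with SNS-314 6 and 6, and the medians of -0.13 and -0.09 did not pass the test (camera adjusted p = 0.505 and 0.650). LMNB1, the nuclear lamina gene whose loss is a marker of senescence, fell by 0.56 ± 0.16 (adjusted p = 0.0039) and fell by 0.64 ± 0.16 (adjusted p = 0.0010). EZH2, a histone methyltransferase, fell with changes of -1.16 ± 0.12 and -1.27 ± 0.12. RBL1, a relative of the retinoblastoma protein, was above background on 3 of 4 control arrays and none at 48 h and fell at least 1.57-fold and 1.60-fold. GLB1, whose product gives the β-galactosidase activity used to stain senescent cells, rose by 0.52 ± 0.10 (adjusted p = 3.9e-05) and 0.54 ± 0.10 (adjusted p = 2.3e-05).

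Lysosome genes, the list that holds GLB1, rose together at 48 h. With AZD1152 24 of 42 members were higher and 1 lower (median 0.34, camera adjusted p = 1.2e-05), and with SNS-314 25 were higher and 1 lower (median 0.43, adjusted p = 2.0e-06), or 25 and 26 higher when adjusted over the list alone. MANBA, a lysosomal mannosidase, rose by 0.86 ± 0.09 and 0.80 ± 0.09. GAA, which breaks down lysosomal glycogen, was above background on all arrays at 48 h and on no control, a rise of at least 1.16-fold and 1.27-fold (adjusted p = 1.2e-04 and 1.1e-05).

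The unfolded protein and amino acid stress list had the highest median at 48 h. Of 27 members, 24 were higher with AZD1152 (median 1.06, camera adjusted p = 6.2e-21) and 23 with SNS-314 (median 1.02, adjusted p = 1.65e-18), or 25 and 24 when adjusted over the list alone. TRIB3, a pseudokinase of the stress response, rose by 2.46 ± 0.17 and 2.21 ± 0.17. DDIT3, which encodes the transcription factor CHOP, rose by 2.37 ± 0.13 and 2.14 ± 0.13, with 2 of 4 control arrays above background. DNAJB9, a chaperone of the endoplasmic reticulum, rose by 2.16 ± 0.14 and 2.06 ± 0.14, and ASNS, which makes asparagine, by 1.90 ± 0.14 and 1.85 ± 0.14. Cholesterol synthesis genes, targets of the factor SREBP2, rose with medians of 0.73 (adjusted p = 7.9e-11) and 0.83 (adjusted p = 5.0e-11), with 15 of 17 members higher for each inhibitor. HMGCS1, an early enzyme of that pathway, rose by 1.92 ± 0.10 and 1.82 ± 0.10, and MSMO1, a later one, by 1.59 ± 0.12 and 1.54 ± 0.12. Ribosome biogenesis genes fell, with 21 of 27 members lower for each inhibitor (medians -0.44 and -0.48, adjusted p = 1.4e-07 and 2.3e-07), or 21 and 22 when adjusted over the list alone. MRTO4 and GRWD1, which act in ribosome assembly, fell with changes of -1.05 ± 0.12 and -0.90 ± 0.10 with AZD1152 and of -0.79 ± 0.12 and -0.94 ± 0.10 with SNS-314. The largest fall was that of ID1, an inhibitor of differentiation factors, by 2.23 ± 0.12 with SNS-314, where 2 of 4 arrays at 48 h were above background. With AZD1152 ID1 was above background on no array at 48 h, a fall of at least 4.51-fold. FABP7, a fatty acid binding protein, was above background on no control array and rose at least 1.84-fold and 1.87-fold.

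Secreted factors of senescent cells did not pass the test as a list at 48 h. With AZD1152 9 of 31 members were higher and 5 lower (median 0.18, camera adjusted p = 0.316), and with SNS-314 11 were higher and 5 lower (median 0.13, adjusted p = 0.379), the same counts as when adjusted over the list alone. GDF15 is also a member of this list. CCL2 was lower with changes of -1.66 ± 0.15 and -1.73 ± 0.15, CXCL1 with changes of -1.45 ± 0.30 and -1.44 ± 0.30, and CXCL8 with changes of -0.58 ± 0.17 and -0.63 ± 0.17. The NF-κB list had medians of -0.22 and -0.24, with 8 and 11 of 24 members lower and 1 and 2 higher. Its calls (adjusted p = 0.032 for both) were lost with an estimated correlation, at adjusted p = 0.315 and adjusted p = 0.302, and the AZD1152 call was lost without its replicate 1 (median -0.20, adjusted p = 0.0544). The interferon list was higher with AZD1152 (median 0.23, 14 of 31 members higher and 3 lower, adjusted p = 0.040, and adjusted p = 0.163 with an estimated correlation). With chip as a block its adjusted p was 0.0533, and the call was lost without AZD1152 48 h replicate 2 (median 0.23) or 3 (0.19) or control replicate 1 (0.23) or 2 (0.25). With SNS-314 the median of 0.19 did not pass the test (adjusted p = 0.135). IFIT1, an antiviral effector, rose by 0.80 ± 0.12 and 0.74 ± 0.12, and IFIH1 rose by 0.73 ± 0.12 and 0.60 ± 0.12.

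Markers of other cell types were examined in the same arrays. The fibroblast markers measured were PDGFRA, PDGFRB, FAP, PRRX1 and TWIST1, while COL1A1, COL1A2, COL3A1, DCN, LUM and THY1 were not measured. Which cells express these markers was not tested. Of the fibroblast markers, 5 of 11 were measured and 4 were higher at 48 h with each inhibitor, with medians of 0.27 (adjusted p = 0.070) and 0.36 (adjusted p = 0.039, and adjusted p = 0.053 with an estimated correlation). At 24 h the medians were 0.16 with both inhibitors, 2 of 5 members were higher, and the list was called (adjusted p = 0.0065 and 0.0458, and adjusted p = 0.014 and adjusted p = 0.0639 with an estimated correlation). At 6 h the medians were below 0, at -0.11 and -0.12, and the list was not called (adjusted p = 0.208 and 0.213), with PRRX1 lower with AZD1152 at -0.37 ± 0.10 (adjusted p = 0.024). The list was not called either at 12 h (medians 0.18 and 0.15, adjusted p = 0.375 and 0.378) or 18 h (medians 0.16 and 0.10, adjusted p = 0.297 and 0.103). At 48 h FAP rose by 0.40 ± 0.10 and 0.43 ± 0.10 and PRRX1 by 0.32 ± 0.09 and 0.35 ± 0.09. Of the keratinocyte markers 2 were measured, KRT10 at 0.21 ± 0.10 and 0.17 ± 0.10 and KRT15 at -0.10 ± 0.10 and -0.04 ± 0.10, and neither was called. KRT10 with AZD1152 was called with chip as a block (0.24) and without AZD1152 48 h replicate 4 (0.27). Leukocyte and endothelial markers were measured by 0 genes each.

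In all, 3791 genes changed at 48 h with AZD1152 (1851 higher, 1940 lower) and 4036 with SNS-314 (1986 higher, 2050 lower), of which 289 and 300 changed at least 2-fold. Within the chips that hold controls the replication medians were -1.33 and -1.34 with AZD1152 and -1.42 and -1.35 with SNS-314, and those of the stress list were 1.05 and 1.03, and 1.04 and 0.95. Calls of the replication, mitosis, Aurora, p53 target, lysosome, stress, cholesterol and ribosome lists at 48 h held with an estimated correlation.

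**Figure D3:**
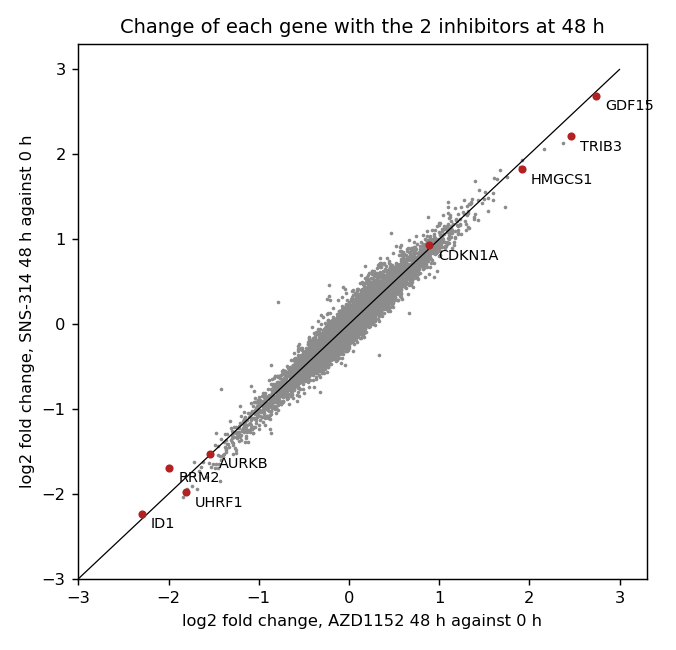
Log2 fold change of each of 8917 genes at 48 h against 0 h with AZD1152 (horizontal axis) and SNS-314 (vertical axis), with equal change on the diagonal line and 8 named genes in red. The points lie along the diagonal with r = 0.967, part of which comes from the shared control arrays, and ID1 is below background at 48 h with AZD1152.

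A direct comparison between 48 h and 6 h within each inhibitor asks whether early and late responses differ. NF-κB target genes were higher at 48 h than at 6 h, with medians of 0.74 (18 of 24 members higher, camera adjusted p = 8.0e-11) with AZD1152 and 0.67 (20 members higher, adjusted p = 2.1e-09) with SNS-314. CCL20, another chemokine gene, rose by 2.31 ± 0.18 and 2.25 ± 0.18 between these times after changes of -2.09 ± 0.18 and -2.12 ± 0.18 at 6 h, and its difference from 0 h at 48 h, 0.22 ± 0.17 and 0.13 ± 0.17, did not pass the test. CXCL8 rose by 1.59 ± 0.19 and 1.66 ± 0.19. Secreted factors rose by medians of 0.45 and 0.47, with 20 and 19 of 31 members higher, and interferon-stimulated genes by 0.38 and 0.46, with 19 of 31 members higher for each inhibitor. The YAP target list was lower at 48 h than at 6 h, with medians of -0.33 and -0.43. These list calls held with an estimated correlation. In all, 3756 genes differed between 48 and 6 h with AZD1152 and 4115 with SNS-314.

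The comparison between the inhibitors at the same time is free of the 0 h control, but the doses differ, 0.5 µM against 0.05 µM. At 48 h limma called 0 genes between AZD1152 and SNS-314 (270 at an unadjusted p under 0.05). The 95% interval of the difference lay within 2-fold for 99.9% of genes and within 1.5-fold for 98.2%, with a median distance of 0.23 from the estimate to either end. These shares also count genes below background in both 48 h groups, such as MKI67 and RBL1, which can differ little. They are on the fitted scale, where a simulated 2-fold difference at 48 h had a median of 0.74, so larger differences in transcripts remain possible. By camera, DNA replication genes were higher with AZD1152 than with SNS-314 at 48 h by a median of 0.10 (adjusted p = 3.2e-04), and p53 target genes were lower by a median of -0.04 (adjusted p = 0.0041), with 0 members called in either list. The mean of the p53 targets differed by -0.07 with a 95% interval from -0.13 to -0.02, and that of the replication genes by 0.07 with an interval from -0.00315 to 0.142. Cholesterol synthesis genes were lower with AZD1152 than with SNS-314 at 24 h by a median of -0.12 (adjusted p = 2.6e-05). These 3 list calls held with an estimated correlation. At 6, 12 and 24 h limma called 0 genes (280, 577 and 297 at an unadjusted p under 0.05). With the replicate number as a block, 1 gene was called at 6 h, CTSZ, a lysosomal cathepsin named after its values were seen, at -1.10 ± 0.21 (adjusted p = 0.043).

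At 18 h 3 genes differed between the inhibitors by limma (1054 at an unadjusted p under 0.05), and all were lower with AZD1152. They are named because they were called, after their values were seen. CXCL8 differed by -1.29 ± 0.17 (adjusted p = 2.4e-05, n = 4 and 4, limma), IL6, which encodes interleukin-6, by -0.72 ± 0.12 (adjusted p = 0.0024) and CCL20 by -0.83 ± 0.17 (adjusted p = 0.039). The NF-κB list was lower with AZD1152 by a median of -0.22 (camera adjusted p = 1.3e-10, and adjusted p = 0.018 with an estimated correlation), with 3 of 24 members lower, or 7 when adjusted over the list alone. Secreted factors and the stress list were lower by medians of -0.05 and -0.10, with calls that were lost with an estimated correlation (adjusted p = 0.307 and adjusted p = 0.498). The 3 genes had fallen against 0 h with both inhibitors. CXCL8 was at -2.60 ± 0.17 with AZD1152 and at -1.31 ± 0.17 with SNS-314 at 18 h, and IL6 at -2.40 ± 0.12 and -1.68 ± 0.12. Without SNS-314 18 h replicate 3 only CXCL8 was called among the 3, with CCL20 at -0.54 ± 0.14 (adjusted p = 0.186) and IL6 at -0.60 ± 0.12 (adjusted p = 0.056). CCL20 also lost its call without AZD1152 18 h replicate 1 (-0.81, adjusted p = 0.103), AZD1152 18 h replicate 4 (-0.72, adjusted p = 0.213) or SNS-314 18 h replicate 2 (-0.81, adjusted p = 0.185). The count of 3 became 78 without AZD1152 18 h replicate 3, 15 without AZD1152 18 h replicate 2, 6 without SNS-314 18 h replicate 4, 14 with chip as a block and 0 with only these 2 groups in the fit. Within the 4 chips CXCL8 differed by -1.58, -1.04, -1.46 and -1.09.

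**Figure D4:**
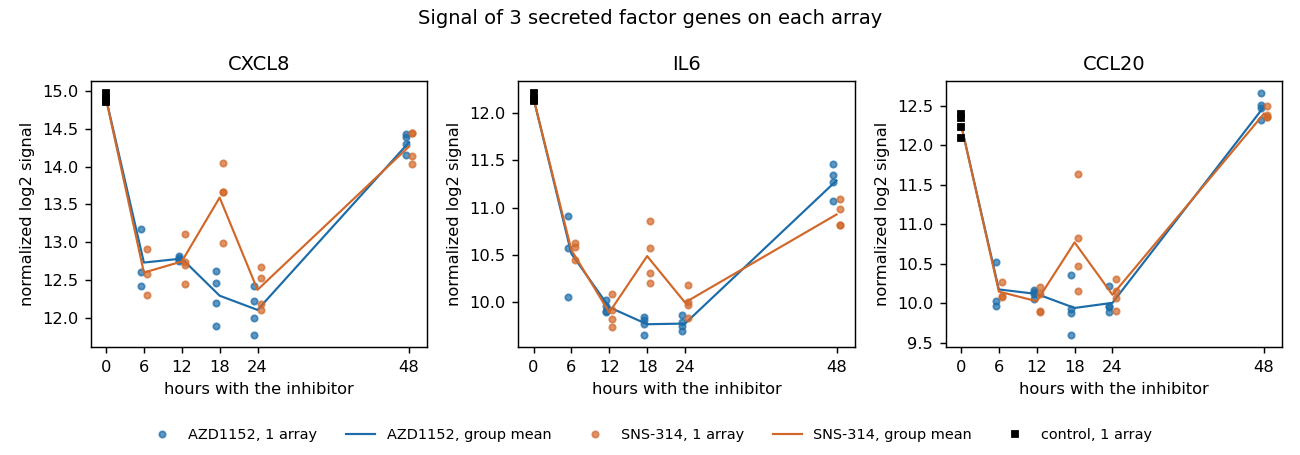
Normalized log2 signal of CXCL8, IL6 and CCL20 against hours with the inhibitor, with 1 point per array, squares for the 4 controls and lines through the group means. Between 6 and 24 h every treated array lies below the controls, and at 18 h the SNS-314 arrays of CXCL8 and IL6 lie above those of AZD1152.

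The changes of both inhibitors from 0 h were set against each other across genes, which are not independent replicates. Pearson's r was 0.780 at 6 h, 0.917 at 24 h and 0.967 at 48 h. Because the same controls enter both sides, simulated unchanged groups gave r of 0.428, 0.497 and 0.500, and with the controls split between the inhibitors r was 0.562, 0.779 and 0.906. The covariance was 0.0320, 0.0684 and 0.175 against simulated values of 0.00744, 0.00739 and 0.00749. The simulations drew the arrays of each inhibitor independently, although arrays of both inhibitors with the same time and replicate number shared a chip. Simulated r and covariance may thus be too low as a reference. At 48 h 1605 genes were higher with both inhibitors, 1712 were lower with both, and 0 changed in opposite directions, counts to which the shared controls contribute. Of the genes called at 24 h, 1109 of 1495 with AZD1152 and 1383 of 1766 with SNS-314 were called in the same direction at 48 h, against 319 and 400 for independent calls. Of those called at 6 h, 58 of 240 and 94 of 331 were called in the same direction at 48 h, against 51.1 and 74.9 for independent calls, and 61 and 88 in the opposite direction. The same controls enter these overlaps and raise those in the same direction, so independent calls are only a rough reference.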

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

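The leave-one-out test of CXCL8 alone, that of the size of the 3 changes at 18 h and the balance of the chips at 18 h were tests chosen only after the result was seen. So were the placing of 18 h arrays by cell cycle genes, the comparison of SNS-314 at 18 h with the 12 and 24 h groups and the look at SNS-314 positions. The other tests here were set before they were run, which is what planned means below. Apart from the splits of the arrays, they name patterns that had already been seen, so they were not set before the data were examined. A test of distance singled out 14 of 276 groups of 4 arrays in which 1 array lay far from the other 3, and chance singles out about 13.8, so the set as a whole is no more than chance gives.

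The first pattern is the change of the transcriptome at 48 h, with 3791 genes called for AZD1152 and 4036 for SNS-314, with the lowest list median for DNA replication genes and the highest for stress genes. At least 99.55% of called genes kept their direction within each chip that holds controls. This share adds little, because the genes were called from these same arrays. Differences between chips are argued against by the replication list, which was not picked from these data. Within these chips its medians were -1.33 and -1.34 with AZD1152 and -1.42 and -1.35 with SNS-314. Position alone is argued against for AZD1152 and its fall of replication and mitosis genes from 24 to 48 h. At positions 9 and 10, 2 AZD1152 arrays of 48 h on chip 1 were set against 4 arrays of 24 h. The 24 h arrays were of both inhibitors and on chips 2 and 4, so chip and inhibitor enter this comparison. The replication list still differed by -0.54 and the mitosis list by -0.65. For SNS-314 position cannot be told apart from time, because 0 of its 4 arrays at 48 h share a position with an array of another time. Time in culture cannot be told apart from the inhibitors, because 0 of the 42 arrays analysed are of untreated cells after 0 h. Of the other ways to split the same arrays, none gave as many genes (1 of 35 splits is the real one, highest other 48 and 310). The same held at 6 h (240 and 331 genes, highest other 86 and 95) and 12 h (381 and 498, 3 and 175). It held also at 18 h (1582 and 867, 129 and 2) and 24 h (1495 and 1766, 5 and 15). A share of 2.86% is the lowest that 35 splits can give, and all 10 comparisons use the same 4 controls. Chance is thus argued against but not excluded.

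The second pattern is the fall of NF-κB target genes at 6 h. A single deviating control array is argued against, since the weakest median without any 1 control was -0.90. Position alone is argued against as well, since the 6 h arrays and the controls at positions 1 and 2 differed by a median of -1.08. These 6 h arrays, an AZD1152 and a SNS-314 array, lay on chip 1 and the controls on chips 2 and 4, so chip enters this comparison. Handling of the cells, such as a change of medium, and time in culture stay open beside the inhibitors and cannot be told apart, with 0 untreated arrays after 0 h among those analysed.

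The third pattern is the difference between the inhibitors at 18 h, where 3 genes, CXCL8, IL6 and CCL20, were lower with AZD1152. An offset of a chip is argued against by the design, since 0 chips hold unequal numbers of 18 h arrays of the 2 inhibitors. The planned count of within-chip differences below 0, 12 of 12, adds little, because these average to the difference for which the genes were picked. The planned test came out for a single array, since only 1 of the 3 genes stayed called without SNS-314 18 h replicate 3. A test chosen later looked at the size of the changes. Without any 1 of the 8 arrays each of the 3 changes stayed below 0, with the highest upper end of a 95% interval at -0.26. The genes were picked for this difference, and the intervals do not allow for that. A single array thus stays open for CCL20 and IL6 and is argued against for CXCL8, which was called in every fit. Without SNS-314 18 h replicate 3, the weakest case, CCL20 was at -0.54 ± 0.14 (-0.83 ± 0.17 with all arrays), IL6 at -0.60 ± 0.12 (-0.72 ± 0.12) and CXCL8 at -1.14 ± 0.18 (-1.29 ± 0.17). Only 1 of the 3 genes, CXCL8, was called there, with a smaller change and 1 array fewer. A lost call does not single out that array: CCL20 lost its call in 4 of 8 fits, and in 3 of them its change was -0.72 to -0.81. IL6 lost it in 1 fit (adjusted p = 0.056), and CXCL8 was called in 8 of 8 (adjusted p = 4.9e-07 to 9.6e-04). For an array from another time point the planned test also came out for that cause, because not all 8 arrays at 18 h matched an 18 h group best. By correlation 5 of 8 arrays at 18 h matched an 18 h group best. SNS-314 replicates 1, 3 and 4 matched AZD1152 12 h, SNS-314 12 h and AZD1152 24 h (r = 0.277, 0.352 and 0.242). With the rest of their own group these SNS-314 arrays had r of 0.143, 0.299 and 0.0275. For AZD1152 arrays 18 h was ahead of other times by 0.0274 to 0.0704. The best 18 h group was not always that of the same inhibitor. AZD1152 replicate 3 matched SNS-314 18 h best (r = 0.363, and 0.0605 with the rest of its own group). SNS-314 replicate 2 matched AZD1152 18 h best (r = 0.301, and 0.229 with the rest of its own group). An exchange of arrays between the inhibitors was not tested and stays open. The means of the replication and mitosis genes, in a test chosen later, argue against an array from another time point. In at least 1 of these means 8 of 8 arrays lay outside the arrays of each other time. They lay at 4.62 SD or more from the mean of those arrays. Mitosis means were 11.32 to 11.62 at 18 h, against 11.65 to 11.82 at 12 h and 11.05 to 11.18 at 24 h. SNS-314 arrays from 12 or 24 h would also lower its values. For each of the 3 genes the SNS-314 18 h mean lay above the highest mean of a 12 or 24 h group, by 0.81 for CXCL8 (95% interval from 0.42 to 1.19), 0.65 for CCL20 (0.28 to 1.03) and 0.49 for IL6 (0.24 to 0.75). The genes were picked because SNS-314 was higher than AZD1152 at 18 h, which favours this outcome, so it does not weigh against such arrays. Chance was not excluded for the count of 3 genes, which 7 of 35 splits reached (highest other 36). A split of chips 2 and 4 against chips 1 and 3 reached it as well, with 3 genes, and with chip as a block the real comparison gave 14. The 3 splits with 33 to 36 genes set both arrays of chip 3 against both of chip 1 or chip 2 and point to a structure between chips. Among the 8 splits with 1 array of each chip on either side, the real one alone reached 3 (highest other 1), and 8 splits are too few for a share under 0.05.

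At the other times limma called 0 genes between the inhibitors (280, 577, 297 and 270 at an unadjusted p under 0.05 at 6, 12, 24 and 48 h), and with 0 genes every split is as large, so the splits say nothing here (10 of 10 at 6 h, highest other 0, and 35 of 35 at each later time). The highest other splits, 330 genes at 12 h and 95 at 24 h, follow the chips and point to a structure between chips, and with chip as a block the comparisons gave 0 genes; at 48 h the highest other was 1.

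Responses at 6 h and 48 h differed for a number of genes and lists, by a direct test of 48 h against 6 h. With AZD1152 61 genes and with SNS-314 88 genes were called in opposite directions at these times with their difference called, 45 of them in both, and 34 and 42 were lower first and higher later. Among them, chosen after their values were seen, IL1A, an inflammatory cytokine, had changes of -1.51 and -1.68 at 6 h and of 0.64 and 0.51 at 48 h, and CEBPD, a transcription factor of inflammation, of -1.52 and -1.36 and then of 0.27 and 0.26. MARCHF4, a ubiquitin ligase, went the other way, from 0.97 and 1.01 to -1.25 and -1.49. For genes called in opposite directions the difference is larger than either change, so its call adds little. The number of opposite calls that independent calls would give was not computed. List medians differed between 48 h and 6 h by 0.45 and 0.47 for secreted factors, by 0.38 and 0.46 for interferon-stimulated genes, and by -0.33 and -0.43 for YAP targets. ERK output differed by 0.15 and 0.23 (adjusted p = 0.0711 and adjusted p = 0.0833 with an estimated correlation), and antigen presentation with SNS-314 by 0.12 (adjusted p = 0.0833 with an estimated correlation).

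The far arrays were as follows. ID1 was 8.32 on AZD1152 48 h replicate 2, above 8.17 to 8.19 on the other 3. RDH10 was 10.74 on control replicate 2, below the others. NNMT was 9.32 on control replicate 1, above the others. CXCL1 was 9.08 on SNS-314 48 h replicate 2, below 9.71 to 9.77. TACC3 was 9.91 on AZD1152 48 h replicate 4, above the others, and IFIH1 was 9.71 on the same array, below 10.11 to 10.14. GAA was 9.13 on SNS-314 48 h replicate 2, above the others, and H4C3 was 13.61 on SNS-314 48 h replicate 1, below the others. H2AC20 was 9.29 on AZD1152 48 h replicate 1, above 8.74 to 8.82, and MSMO1 was 12.04 on AZD1152 48 h replicate 2, below 12.42 to 12.48. The mean of interferon-stimulated genes was 10.43 on SNS-314 48 h replicate 3, above the others, and that of extracellular matrix genes was 11.65 on AZD1152 48 h replicate 3, below the others. The share of probes above background was 22.4% on AZD1152 12 h replicate 2 and 23.7% on SNS-314 18 h replicate 2, both below their groups.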

How the results depend on the processing

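Chip as a fixed block, leaving out 3 arrays together, and all alternatives for the NF-κB, Aurora, stress, cholesterol and ribosome lists were chosen only after seeing the data. No list shift changed direction in any alternative run, nor did a named gene called at 48 h against 0 h. Of 296 counts of changed genes 267 stayed within 1.5 times the reported count, and of 674 list shifts 651 kept direction and side of the threshold. Of 2520 values of named genes 2511 stayed the same. For a called gene this means the same direction and side of the threshold. Values called in neither run, among them all differences of the inhibitors at 48 h that stayed uncalled, had to lie within 1 SD, with no check of direction. At 48 h the counts ranged from 2818 to 4294 for AZD1152 and from 3022 to 4480 for SNS-314, and at 24 h from 1060 to 1887 and from 1252 to 2188. With no filter on dim probes the counts were 222 (AZD1152 12 h), 315 (SNS-314 12 h) and 1 (difference of the inhibitors at 48 h), and their changes correlated with r of 0.654, 0.832 and 0.914 at 6, 24 and 48 h. With split controls r was 0.562, 0.779 and 0.906, which removes the shared controls. With only the groups compared, and so fewer arrays behind the spread, the counts were 551 (AZD1152 18 h), 240 (SNS-314 12 h), 0 (difference at 18 h) and 1 (difference at 48 h). With the replicate block they were 576 and 794 (12 h), 1 (difference at 6 h) and 12 (difference at 18 h). The replicate numbers did not pair the arrays with the 0 h controls (residual r from -0.17 to 0.388), so that block is not used for them. The difference at 18 h held 13 genes with chip as a random block, 14 with chip fixed, and 1 without the 3 arrays that stand apart (AZD1152 18 h replicates 1 and 4, SNS-314 12 h replicate 4), where AZD1152 18 h gave 663. Restricted to probes above background on every array, SNS-314 6 h gave 217 genes, and the list medians below lost their call: interferon at 24 h, -0.12 and -0.13; lysosome with AZD1152 at 24 h, 0.068; NF-κB at 48 h, -0.19 and -0.26. Calls were also lost for lysosome with AZD1152 at 24 h with 75th percentile scaling (0.070), and for interferon with AZD1152 at 48 h with the mean over probes (0.23) and with chip fixed (0.21). With an estimated correlation, which leaves the medians as they were, calls were lost for interferon at 24 h (-0.15 and -0.13), lysosome with AZD1152 at 24 h (0.070), interferon with AZD1152 at 48 h (0.23) and NF-κB at 48 h (-0.22 and -0.24). These losses, and the 674 shifts above, cover only the lists and times for which alternatives were set. Of 21 lists tested at 24 h, 13 (AZD1152) and 12 (SNS-314) were called with the preset correlation and 7 and 8 with both, and at 48 h 11 were called with the preset and 8 with both for each inhibitor. Leaving out 1 array gave 141 to 216 genes for AZD1152 at 6 h, 236 to 327 at 12 h and 1002 to 1935 at 18 h. It gave 218 to 286 for SNS-314 at 6 h, 293 to 695 at 12 h, and 2 to 78 for the difference at 18 h. Lysosome medians with AZD1152 at 24 h ran from 0.043 to 0.097, interferon medians with AZD1152 at 48 h from 0.19 to 0.26, and NF-κB medians with AZD1152 at 48 h from -0.24 to -0.17. The calls of ERBB3 (0.18 with the mean over probes), RDH10 (-0.30 to -0.32 without AZD1152 48 h replicate 3 or 4 or control replicate 1, 3 or 4) and NNMT (0.51 without AZD1152 48 h replicate 4) at 48 h with AZD1152 were lost in those settings. Except where stated, the cause was not tested. Signal over background limits the dim genes: between 20.5% and 30.4% of probes lay above background, and bounds replace folds where a group lay below it.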

Other observations

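The test of mitosis against replication genes below was chosen only after the result was seen. Extracellular matrix genes did not pass the test as a list at 48 h, with 11 of 26 higher and 4 lower with AZD1152 (median 0.14, camera adjusted p = 0.168) and 9 higher and 4 lower with SNS-314 (median 0.16, adjusted p = 0.135), or 12 and 9 higher and 5 lower when adjusted over the list alone. VCAN, which encodes the proteoglycan versican, rose by 0.91 ± 0.14 and 0.87 ± 0.14, and THBS1, a matrix glycoprotein and YAP target, fell with changes of -0.81 ± 0.14 and -0.79 ± 0.14. The YAP list, higher at 6 h, had medians of -0.02 and -0.06 at 48 h (adjusted p = 0.364 and 0.379), and WWC1, a regulator of the Hippo pathway, fell with changes of -0.88 ± 0.13 and -0.93 ± 0.13. ERK output had medians of 0.05 and 0.08 (adjusted p = 0.364 and 0.379); EGR1, an early response transcription factor, fell with changes of -0.45 ± 0.12 and -0.42 ± 0.12 at 6 h and rose by 0.66 ± 0.11 and 0.64 ± 0.11 at 48 h. The hypoxia list was called at 48 h with medians of 0.20 and 0.23 (adjusted p = 0.037 and 0.039, and adjusted p = 0.107 and adjusted p = 0.119 with an estimated correlation). P4HA1, a collagen prolyl hydroxylase, rose by 0.77 ± 0.09 and 0.85 ± 0.09, and DDIT4, an inhibitor of mTOR signalling, by 1.34 ± 0.10 and 1.41 ± 0.10.

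Melanocyte genes were mostly below background, with 8 of 28 measured and medians of 0.06 with both inhibitors at 48 h (adjusted p = 0.444 and 0.379). ERBB3, a receptor kinase of the neural crest lineage, rose by 0.60 ± 0.11 and 0.85 ± 0.11, with 3 of 4 controls above background, and MC1R, the melanocortin receptor, fell with changes of -0.53 ± 0.10 and -0.50 ± 0.10. Antigen presentation had medians of -0.04 and 0.04 (adjusted p = 0.444 and 0.379), while HLA-DMB, which loads peptides on class II molecules, rose by 0.96 ± 0.12 and 0.84 ± 0.12. Pro-death apoptosis effectors had medians of 0.22 and 0.21 (adjusted p = 0.318 and 0.379). BNIP3L, a mitophagy receptor, rose by 0.62 ± 0.11 and 0.71 ± 0.11, and CASP9, an initiator caspase above background on 1 of 4 controls, rose by 0.52 ± 0.10 and 0.66 ± 0.10. Of the replication-dependent histones, 6 were measured, with medians of -0.57 and -0.61 (adjusted p = 0.125 and 0.135), 2 higher and 3 or 4 lower. H4C3 fell with changes of -0.93 ± 0.09 and -1.11 ± 0.09 and H2AC20 with changes of -1.02 ± 0.13 and -0.98 ± 0.13.

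At 12 h replication genes were lower and mitosis genes higher. A candidate explanation is that cells were held after replication and before or in division, where Aurora kinases act, but no test here decides it. The mean of the mitosis genes minus that of the replication genes only restates the 2 list results. It was higher by 0.48 with AZD1152 and by 0.52 with SNS-314, above every control on 4 of 4 arrays for each (exact two-sided permutation p = 0.0286, the smallest that 4 against 4 can give, and 0.0357 adjusted over 10 comparisons). At 6 h the differences were 0.02 and 0.03 (exact permutation p = 0.600 and 0.743), at 18 h 0.55 and 0.62, and at 48 h, where both lists were lower, 0.33 and 0.41. A fall of replication genes alone also raises this difference, and at 12 h their mean had changes of -0.25 and -0.30, beside 0.22 for the mitosis genes with each inhibitor. Time in culture stays open at all times. Cells were not counted by cycle phase here.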
